A study of Mus musculus with 6 samples.

How the data were processed

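The series holds lungs of mice injected intravenously with B16-F10 melanoma cells, 3 libraries from WT and 3 from Tmem175-/- mice, 1 per numbered model in the titles, and the mouse is taken as the replicate. Lungs were digested to single cells and libraries of transcript 5′ ends were made on the Chromium platform, per the labels' protocols. The values are counts: the deposited matrices hold the number of UMIs per gene and barcode for 33696 genes, unfiltered and not normalized, and the authors made them with Cell Ranger. Its version is 9.0.0 per the file headers and 2.1.1 per the submitters' processing notes, which also name the GRCm39 genome. Reads counted to near-identical genes and the treatment of intronic reads are not given in the sources used here.

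Everything below was computed from those counts with Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. A barcode was kept as a cell with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. Doublets were called per library with scrublet at an expected rate of 0.06, and 3686 barcodes were removed. In WT 1, WT 3 and Tmem175-/- 2 its automatic threshold marked under 0.5% of cells, so the 5% with the highest scores were removed there. This left 85176 cells. The total UMIs per library were 118344234, 126432835 and 112987460 in WT and 103444494, 88986467 and 96638957 in Tmem175-/-, and the median genes per cell were 1337, 1374 and 1362 in WT and 1348, 1386 and 1321 in Tmem175-/-. At this depth, a gene with no UMI in a library's cells lies under 0.0272 to 0.0397 CPM (3 counts, counting error only).

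Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at a resolution of 1.5 gave 49 clusters, with no integration between libraries. No cell annotation was used from the authors. Clusters were named from marker lists of 20 broad and 34 fine classes. The scoring was set after seeing the data. A marker counted with 2-fold over other cells (pseudocount 20 CPM) in at least 10% of a cluster's cells, 3 markers were needed, and a cluster stayed unnamed where its score for another broad class reached a share of 0.6 of the best score. Where a sibling class reached 0.8, the cluster kept the broad name alone and is named by its leading gene. Clusters also stayed unnamed where more leading genes marked another class, where UMIs were low with no leading marker, or where leading genes were those of immature thymocytes. Of the clusters 6 stayed unnamed, with 10.8, 3.95 and 15.4% of the cells of the WT libraries and 13, 0.98 and 0.82% of those of Tmem175-/-.

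UMIs were summed per library and class, so that n = 3 libraries per genotype. Genes were tested with edgeR's quasi-likelihood test (robust fit, TMM factors, filterByExpr) within each of the 15 broad and 10 fine classes with at least 20 cells in every library, and over all cells, with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. Genes past it are said to have risen, fallen or been called. Fold changes are Tmem175-/- over WT in log2, and their SE is the absolute log2 fold change over the square root of the F statistic. Cell numbers were tested in the same way, with the log of all named cells as offset and no TMM, in 17 broad and 28 fine classes with at least 10 cells on average per library. Gene lists, 38 fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 508 pairs of list and class with 5 or more tested genes, with camera at an estimated correlation and fry as alternatives. Whether the genotype effect differed between 2 classes of the same libraries was tested as an interaction with the library as a block. The scripts were tested on simulated data made from the real means and library sizes. Of 100 genes changed 4-fold, edgeR recovered 95% over all cells, 94% in monocytes or interstitial macrophages, 98% in T cells, 96% in melanoma cells and 82% in plasmacytoid dendritic cells, and of 100 changed 2-fold 44%, 66%, 79%, 73% and 49%. In cell numbers simulated at a set dispersion, a 4-fold fall of melanoma cells alone was recovered in 96% of 50 runs. Changes in rarer classes were not simulated.

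Free RNA was estimated per library from barcodes with at most 100 UMIs, scaled in each class by melanocyte and epithelial genes, which the class itself is not meant to express. A gene has a high free RNA share where the expected free counts exceed 25% of the class's counts in either genotype. It was not subtracted. Genes with groups apart are those whose 3 values in one genotype all lie above the 3 of the other. Libraries were compared with one another by a chi-square of their counts, which per degree of freedom was 74.5 to 235 within a genotype and 371 to 773 between genotypes, so no library repeats another.

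The rule for named genes was set before the data were examined, as were the marker lists, gene lists, tests and the first set of alternatives. It takes Tmem175, then for all cells and each broad class up to 12 called genes with the highest and 12 with the lowest fold change whose groups lie apart (5 each way after the first 3 classes), genes called in the same direction in 3 or more broad classes, and called members of each list that passes. Predicted genes, mitochondrial and ribosomal protein genes and receptor V, D and J segments are counted and not named. Not every gene the rule takes is printed, 1 gene is not reported here, and genes outside it are said to be chosen after their values were seen. Those alternatives were RLE factors, DESeq2, no filter on low counts, the replicate number as a block, each library left out in turn, 1000 UMIs per cell, 5% mitochondrial UMIs, doublets kept, genes without a high free RNA share, other denominators and tests of the shares, and a Leiden resolution of 2.5. Alternatives chosen after seeing the data were leaving out WT 3 and Tmem175-/- 1 together, named cells alone, and denominators without melanoma cells, without B cells and the T cell group led by Lef1, and with unnamed cells. All alternatives run on the fine classes were also added then, as were the free RNA filter for named genes, for the lists and for the difference between classes. Genomic coordinates are not given, since the annotation of the named genome was not used here. The order of genes around Tmem175 comes from the GRCm38.p6 gene table and the GC of the first 200 bases from GRCm38 annotation. Figures were drawn with matplotlib 3.10.9.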

Results

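Lungs of 3 WT and 3 Tmem175-/- mice that had received B16-F10 cells intravenously were profiled by droplet-based single-cell RNA sequencing of transcript 5′ ends, with 1 library per numbered model. B16-F10 is a mouse melanoma line that forms nodules in the lung after injection into the blood. Tmem175 encodes an ion channel of the lysosome, so the comparison of the genotypes asks how its loss in the host alters the cells of a lung that holds metastases. The files held 88986467 to 126432835 UMIs per library, and 75549973 to 110425294 of them lay in the 85176 barcodes kept as cells. The 3 WT libraries gave 12303, 15044 and 12747 cells, and the 3 Tmem175-/- libraries gave 16394, 13961 and 14727 cells. The median UMIs per cell were 2920, 3164 and 2839 in WT and 3019, 3342 and 3193 in Tmem175-/-. Within classes they could differ more, with 2292, 1996 and 2649 against 2868, 3489 and 3028 in T cells and 6748, 5917 and 7021 against 8923, 8984 and 8056 in dendritic cells. Marker genes fixed before the data were examined named 78914 of the cells. Measures of quality differed between the genotypes. Barcodes removed for mitochondrial UMIs made up 3.36, 2.28 and 4.67% in WT and 0.94, 1.22 and 1.5% in Tmem175-/-, and cells of 500 to 999 UMIs numbered 1870, 1472 and 2671 against 1045, 702 and 860. For RNA free in the suspension, the expected share of the UMIs of T cells was 12.3, 11.1 and 10.7% in WT and 3.15, 2.74 and 3.65% in Tmem175-/-, and in all 15 classes tested for genes the mean share was higher in WT.

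Tmem175, the targeted gene, was detected in every library. Over all cells it lay at 14.8, 13.5 and 16 CPM in the WT libraries (1468, 1491 and 1494 UMIs) and at 13.6, 14 and 11.2 CPM in the Tmem175-/- libraries (1248, 1057 and 928 UMIs). The means of 14.8 ± 1.26 and 12.9 ± 1.52 CPM (SD, n = 3) differed by a log2 fold change of -0.13 ± 0.13 (SE), with an adjusted p of 0.451 in edgeR's quasi-likelihood test. In alveolar macrophages Tmem175 lay at 6.81 ± 0.931 CPM in WT and 4 ± 1.85 CPM in Tmem175-/- (log2 fold change -0.88 ± 0.31, adjusted p = 0.241), and in fibroblasts at 11.7 ± 0.721 and 14.8 ± 0.766 CPM (0.37 ± 0.15, adjusted p = 0.183). In T cells it lay at 16.9 ± 2.88 and 15 ± 0.857 CPM (-0.07 ± 0.15, adjusted p = 0.849). In the melanoma cells, which came from the injected line, Tmem175 lay at 17.4 ± 1.45 and 17.3 ± 2.05 CPM. These cells gave 1075, 955 and 1009 of its UMIs in WT, most of them, and 396, 189 and 324 in Tmem175-/-. The values over all cells therefore mix the genotype of the host with the share of melanoma cells. The kit counts transcript 5′ ends and the labels do not name the deleted part of the gene, and a 5′ tag outside the deleted part checks nothing. The genotypes are therefore taken from the labels alone.

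The question for the cell classes was which cells were more or less frequent in the Tmem175-/- lung. Melanoma cells made up 14.7 ± 2.36% of named cells in WT and 3.3 ± 1.2% in Tmem175-/- lungs (SD, n = 3), a log2 fold change of -2.15 ± 0.36 (SE, adjusted p = 0.0016). The shares per library were 16.9, 12.2 and 14.9% in WT and 4.19, 1.94 and 3.77% in Tmem175-/-. NK, T and B lymphocytes took larger shares of the named cells of Tmem175-/- libraries. NK cells went from 2.14 ± 0.732 to 5 ± 1.9% (log2 fold change 1.23 ± 0.38, adjusted p = 0.024). T cells went from 11.8 ± 1.36 to 22.7 ± 5.44% (0.94 ± 0.30, adjusted p = 0.024) and B cells from 10.8 ± 0.668 to 19.9 ± 7.9% (0.88 ± 0.33, adjusted p = 0.0452). Per library, B cells lay at 10.1, 11.5 and 10.9% in WT and 13.4, 28.7 and 17.5% in Tmem175-/-. Plasma cells, the antibody secreting descendants of B cells, went from 0.28 ± 0.229 to 1.5 ± 0.669% (2.39 ± 0.61, adjusted p = 0.024). Structural cells took smaller shares. Fibroblasts lay at 13.8 ± 0.679 and 7.11 ± 1.06% (-0.96 ± 0.28, adjusted p = 0.024). Mural cells lay at 2.07 ± 0.383 and 1.05 ± 0.205% (-0.97 ± 0.31, adjusted p = 0.024), and mesothelial cells at 2.38 ± 0.549 and 1.21 ± 0.309% (-0.97 ± 0.32, adjusted p = 0.0253). Platelets or megakaryocytes fell from 0.188 ± 0.127 to 0.0606 ± 0.0161% (-1.59 ± 0.51, adjusted p = 0.024), and their cluster had a median of 750 UMIs. With at least 1000 UMIs per cell they numbered 4, 5 and 7 in WT and 5, 2 and 4 in Tmem175-/-. The other 8 of the 17 classes did not pass, among them neutrophils, monocytes or interstitial macrophages, and dendritic cells. Endothelial cells lay at 5.77 ± 4.57 and 2.24 ± 0.763% (adjusted p = 0.0531) and alveolar macrophages at 10.7 ± 1.9 and 7.06 ± 4.05% (adjusted p = 0.232).

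**Figure D1:**
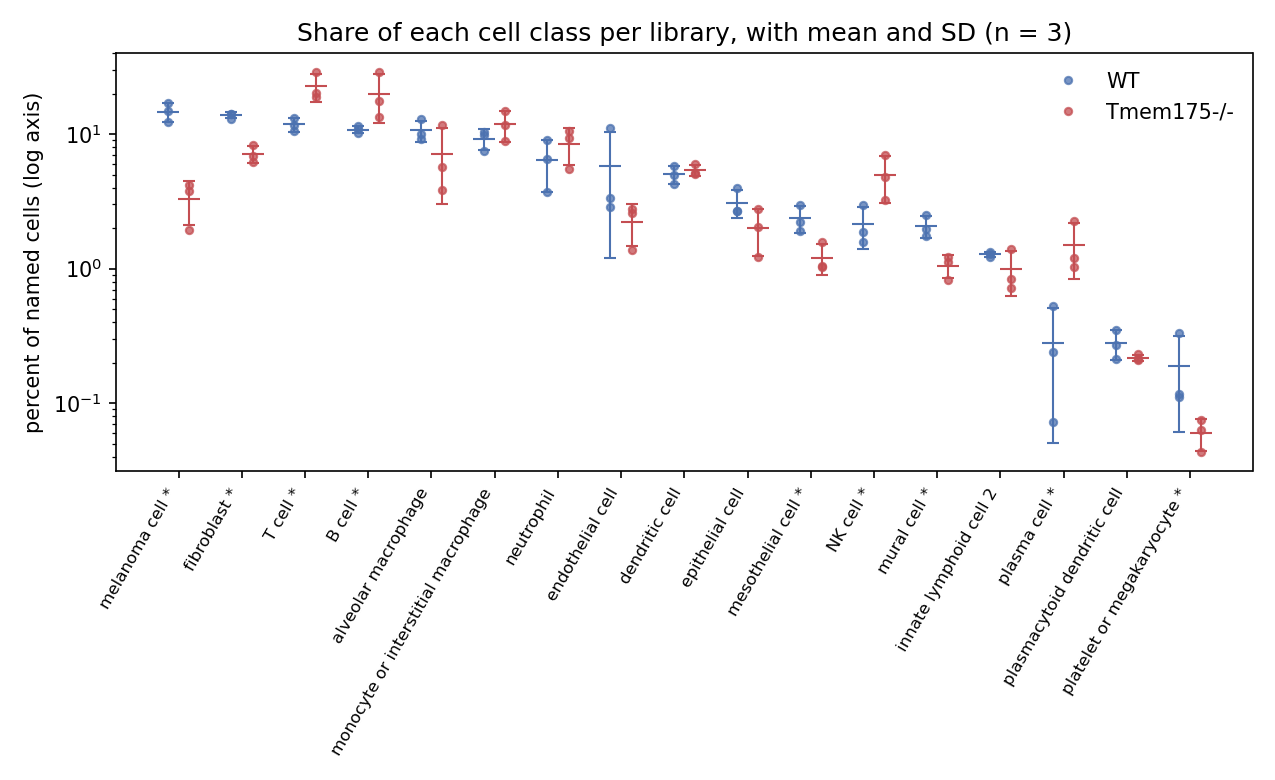
Percent of named cells in each broad class (log axis) for the 3 WT and 3 Tmem175-/- libraries, with points for libraries, long ticks for means and bars for SD; an asterisk marks an adjusted p under 0.05 in edgeR's test of cell numbers. Melanoma cells lay at 12.2 to 16.9% in WT and 1.94 to 4.19% in Tmem175-/-, while T, B, NK and plasma cells lay higher and fibroblasts, mural and mesothelial cells lower in Tmem175-/-.

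These shares depend on one another, since they sum to the whole lung sample. With immune cells alone as the denominator, the changes were 0.69 in NK cells (adjusted p = 0.21), 0.40 in T cells (0.341) and 0.34 in B cells (0.428), all log2 and no longer past the threshold. The change in plasma cells stayed past it at 1.88 ± 0.55 (adjusted p = 0.0475). The 3 WT and 3 Tmem175-/- values did not overlap for any of the 9 called classes, and an exact two-sided permutation test gave p = 0.1, the smallest p that 3 libraries against 3 allow. The melanoma call held whichever library was left out. The number of calls, 9 with all libraries, was 4 without WT 2, 3 without WT 3, 2 without Tmem175-/- 2 and 5 without Tmem175-/- 3. The NK call ended without WT 2 (adjusted p = 0.0653) or Tmem175-/- 1 (0.0813). The T cell call ended without WT 1 (0.0563), WT 2 (0.1), WT 3 (0.0601), Tmem175-/- 2 (0.0592) or Tmem175-/- 3 (0.064). The B cell call ended without WT 1 (0.121), WT 2 (0.0877), WT 3 (0.0805), Tmem175-/- 2 (0.155) or Tmem175-/- 3 (0.0699). Those of plasma cells ended without WT 3 (0.0711) or Tmem175-/- 2 (0.0592), and those of platelets without WT 3 (0.113), Tmem175-/- 1 (0.086) or Tmem175-/- 2 (0.106). Among structural cells, the fibroblast call ended without WT 1 (0.062), WT 2 (0.0713), Tmem175-/- 2 (0.0591) or Tmem175-/- 3 (0.0699). For mural cells these were WT 2 (0.0653), WT 3 (0.0711), Tmem175-/- 2 (0.0592) and Tmem175-/- 3 (0.0699). For mesothelial cells they were WT 2 (0.131), WT 3 (0.0567), Tmem175-/- 2 (0.0716) and Tmem175-/- 3 (0.0997). Endothelial cells passed without WT 1 (0.0051) or WT 2 (0.00201), and alveolar macrophages without Tmem175-/- 3 (0.0479). Cells left unnamed made up 10.8, 3.95 and 15.4% of the WT libraries and 13, 0.98 and 0.82% of the Tmem175-/- libraries. In Tmem175-/- 1 they included 1893 cells of a cluster led by Rag1 and Dntt, as in immature thymocytes. The shares cannot tell lymphocytes of the lung from those of other tissue in the suspension.

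Among the finer classes, several groups of T cells took larger shares. A group of dividing T cells, led by the histone genes H2ac23 and H1f5 and by Pclaf, Mki67 and Top2a, rose from 0.279 ± 0.00739 to 1.04 ± 0.103% of named cells (log2 fold change 1.89 ± 0.22, adjusted p = 0.00205). This call held whichever library was left out and with immune classes as the denominator (1.38 ± 0.26, adjusted p = 0.0104). CD8 T cells, here a cluster led by Ccl5 and Gzmk, went from 1.51 ± 0.485 to 3.78 ± 0.135% (1.32 ± 0.29, adjusted p = 0.0253) and regulatory T cells from 1.03 ± 0.336 to 2.74 ± 1.16% (1.41 ± 0.40, adjusted p = 0.039). A T cell group led by Il17a, Cxcr6, Icos and Scart1 went from 2.49 ± 0.175 to 4.16 ± 0.261% (0.74 ± 0.20, adjusted p = 0.039). With immune classes as the denominator these 3 were not called, at 0.78 (adjusted p = 0.0994) in CD8, 0.87 (0.101) in regulatory and 0.22 (0.461) in Il17a T cells. At a Leiden resolution of 2.5 part of the group led by Lef1 was named CD8 as well, and CD8 T cells numbered 331, 415 and 391 in WT and 953, 1422 and 1069 in Tmem175-/-, against 116, 211 and 218 and 557, 525 and 531 here. Classical monocytes lay at 2.56 ± 1.32 and 5.99 ± 1.79% (1.23 ± 0.48, adjusted p = 0.0774) and did not pass. The CD8 call ended without WT 1 (adjusted p = 0.0578), WT 2 (0.0638), Tmem175-/- 2 (0.0506) or Tmem175-/- 3 (0.0713). The call of regulatory T cells ended without any of the 6 libraries, at adjusted p values of 0.0578 (WT 1), 0.0869 (WT 2), 0.0923 (WT 3), 0.066 (Tmem175-/- 1), 0.0839 (Tmem175-/- 2) and 0.0682 (Tmem175-/- 3). That of Il17a T cells ended without WT 1 (0.104), WT 2 (0.0817), WT 3 (0.0805), Tmem175-/- 2 (0.083) or Tmem175-/- 3 (0.109). Of the 28 finer classes 10 were called, and 2 without WT 1, 3 without WT 2, 5 without WT 3 and 2 each without Tmem175-/- 2 or Tmem175-/- 3.

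Over all cells summed per library, 4363 genes rose and 4295 fell in Tmem175-/- lungs among 20650 tested, a comparison that mixes expression with cell composition. The genes with the largest increases included Gp2, a glycoprotein of mucosal epithelium (0.114 ± 0.052 and 3.03 ± 1.26 CPM, log2 fold change 4.81 ± 0.43, adjusted p = 0.000586). Another was Itln1, an epithelial lectin that binds microbial sugars (7.19 ± 1.24, adjusted p = 0.00807). Ubd, an interferon-inducible ubiquitin-like modifier, rose (4.46 ± 0.61, adjusted p = 0.00157), as did Ighg3, an immunoglobulin heavy chain constant region gene (4.06 ± 0.77, adjusted p = 0.00894), whose reads can be shared with sister constant regions and are uncertain. The histone gene H4c17 had the largest change (0.0529 ± 0.0289 and 10.8 ± 2.14 CPM, 7.71 ± 0.35, adjusted p = 0.000137), and it too belongs to a family of near-identical copies. Among genes with the largest decreases were Gucy2f, a photoreceptor guanylate cyclase (-2.34 ± 0.26, adjusted p = 0.000908), Cer1 (-2.15 ± 0.33, adjusted p = 0.00222) and Btn2a2, a butyrophilin that restrains T cells (-2.02 ± 0.37, adjusted p = 0.00415). Aire, a transcription factor of self-antigen display, fell from 2.44 ± 1.75 to 0.457 ± 0.222 CPM (-2.30 ± 0.55, adjusted p = 0.0143). Without WT 1 the calls were 5256.

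In the class of monocytes or interstitial macrophages, the recruited and tissue macrophages outside the airspaces, 1227 genes rose and 1216 fell among 12056 tested. Genes of the interferon response and of antigen display rose together. Of 42 type I interferon stimulated genes, 34 rose (35 adjusted over the list alone). Among them was Irf7, a transcription factor that amplifies interferon production (log2 fold change 2.08 ± 0.24, adjusted p = 0.00174). Oas1g, a sensor of double-stranded RNA, rose too (1.77 ± 0.16, adjusted p = 0.000119). Of 22 genes of MHC class I presentation, 19 rose and 1 fell (19 and 2 adjusted over the list alone). H2-K1 lay at 1190 and 2320 CPM (1.05 ± 0.11, adjusted p = 0.000231), the peptide transporter Tap1 at 1.51 ± 0.13 and B2m, the light chain of class I molecules, at 0.58 ± 0.10. The member that fell was Calr, a chaperone of the endoplasmic reticulum. In the list of the interferon gamma response 21 of 30 rose (25 adjusted over the list alone), and 7 of 12 MHC class II genes rose (7 adjusted over the list alone), with H2-Ab1 at 0.81 ± 0.12. The adjusted p of these 4 lists with an estimated correlation was 0.325, 0.315, 0.321 and 0.527. Among the largest increases were C6, a terminal complement component (3.73 ± 0.544 and 24.2 ± 3.01 CPM, 2.76 ± 0.18, adjusted p = 4.25e-05), and Lyz1, a lysozyme gene of mucosal tissue (121 ± 33.7 and 602 ± 116 CPM, 2.41 ± 0.21, adjusted p = 0.00029). The genes with the largest decreases, such as Pax3, a regulator of the melanocyte lineage (-2.57 ± 0.32), and Bnc2 (-2.96 ± 0.28), were ones whose expected free RNA share exceeded 25% in this class.

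Some genes of lysosomal digestion and of alternatively activated macrophages fell in the same class. Of 44 lysosomal hydrolase genes, 9 fell and 4 rose (17 and 5 adjusted over the list alone). The aspartic protease Ctsd went from 1600 to 730 CPM (log2 fold change -1.04 ± 0.11, adjusted p = 0.000256). The cysteine protease Ctsl changed by -0.68 ± 0.10 (adjusted p = 0.00109), and the acid phosphatase Acp5 by -1.05 ± 0.20 (adjusted p = 0.00757). Of 28 genes of lysosomal membrane proteins and the V-ATPase, the proton pump that acidifies the lysosome, 8 fell and 1 rose (9 and 1 adjusted over the list alone). Its subunit gene Atp6v0d2 went from 63.8 to 16.8 CPM (-1.81 ± 0.20, adjusted p = 0.000771), and the tetraspanin gene Cd63 from 938 to 449 CPM (-0.97 ± 0.11, adjusted p = 0.000266). Atp6v0d2 is also among the markers used here to name alveolar macrophages. Whether RNA or cells of that class add to its level here was not tested. The adjusted p of these lists with an estimated correlation was 0.639 and 0.444. The list of lysosomal ion channels was not called, with 0 of 17 up and 2 down by edgeR. Of 31 genes of alternatively activated macrophages, 12 fell and 3 rose (13 and 4 adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). These included Spp1, which encodes osteopontin (671 and 160 CPM, -1.98 ± 0.25, adjusted p = 0.00241), and Lyve1, a hyaluronan receptor of perivascular macrophages (171 and 45.3 CPM, -1.83 ± 0.24, adjusted p = 0.0028). The elastase Mmp12 (-1.47 ± 0.23, adjusted p = 0.00497), the fatty acid receptor Cd36 (-1.04 ± 0.15, adjusted p = 0.0014) and the lipid receptor Trem2 (-0.73 ± 0.11, adjusted p = 0.00134) fell too. In the proliferation list 22 of 32 genes fell (25 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation), with Stmn1 at -0.64 ± 0.13. Free RNA was expected to give 7.58, 11.6 and 7.11% of this class's UMIs in WT and 2.87, 2.5 and 3.29% in Tmem175-/-. The value of WT 2 is uncertain, since scaling by epithelial genes gave 5120 melanocyte UMIs there and 1529 were observed. Among genes without a high free RNA share 1161 rose and 767 fell.

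**Figure D2:**
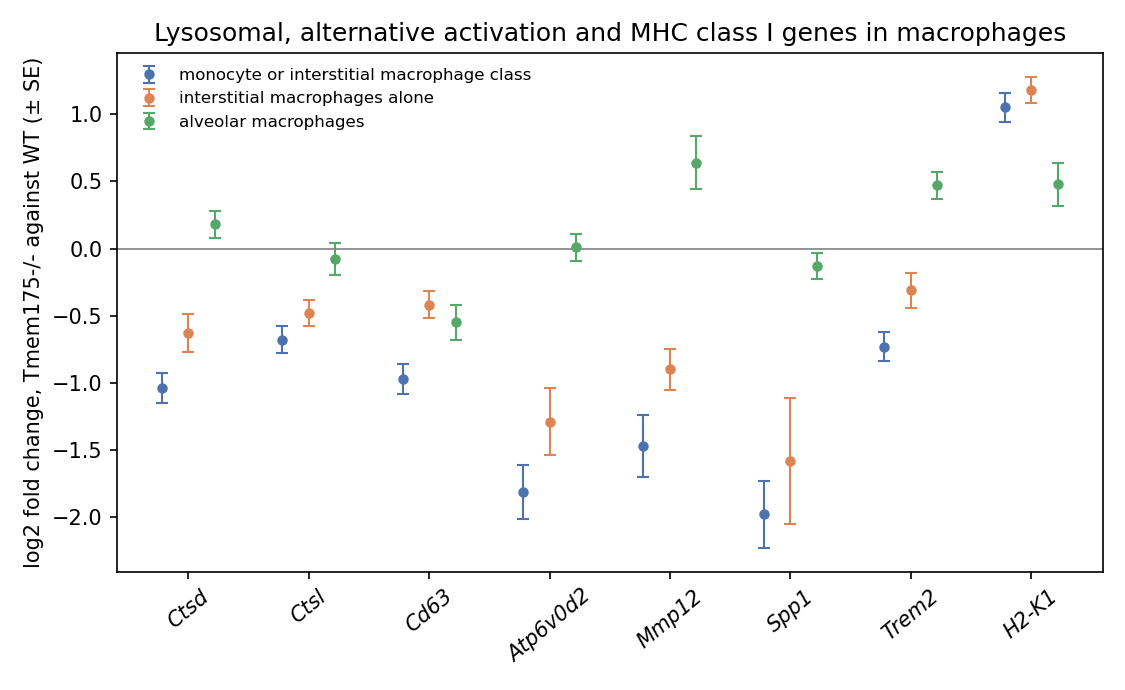
Log2 fold change of Tmem175-/- against WT, with its SE, for 8 genes in monocytes or interstitial macrophages together, in interstitial macrophages alone and in alveolar macrophages (n = 3 libraries per genotype). Ctsd changed by -1.04, -0.63 and 0.18 in these, in that order.

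Classical monocytes made up more of this class in Tmem175-/- lungs, with a cluster of 303, 545 and 124 cells in WT and 1086, 563 and 920 in Tmem175-/-. At a Leiden resolution of 2.5 classical monocytes numbered 204, 417 and 57 against 766, 402 and 610, and nonclassical monocytes 97, 130 and 66 against 332, 161 and 322. Interstitial macrophages were therefore also tested alone, with genes chosen after their values were seen. In them 572 genes rose and 307 fell among 11115 tested. H2-K1 and C6 kept their size, with H2-K1 at a log2 fold change of 1.18 ± 0.10 (adjusted p = 7.56e-06) and C6 at 3.31 ± 0.18 (adjusted p = 1.47e-07). Fabp5, a fatty acid binding protein, fell from 1230 to 494 CPM (-1.22 ± 0.15, adjusted p = 0.000801), and Mmp12 by -0.90 ± 0.15 (adjusted p = 0.00392). Ctsd lay at 1970 and 1200 CPM (-0.63 ± 0.14, adjusted p = 0.0188), a call that ended without WT 1 (adjusted p = 0.0899), WT 2 (0.0636), Tmem175-/- 1 (0.0814) or Tmem175-/- 2 (0.0697). Spp1 lay at -1.58 ± 0.47 (adjusted p = 0.146) and was not called. In classical monocytes alone Ctsd lay at -0.17 ± 0.13 (adjusted p = 0.574). The count for the whole class, 2443 in all, was 1253 without WT 1, 1533 without Tmem175-/- 1 and 1518 without Tmem175-/- 2. The 879 calls of interstitial macrophages were 331 without WT 1, 480 without Tmem175-/- 1 and 381 without Tmem175-/- 2.

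Alveolar macrophages, the resident phagocytes of the airspaces, differed in far fewer genes, with 32 up and 89 down among 11246 tested. Of these calls 25 up and 8 down were without a high free RNA share, and 12 genes were called when such genes alone were tested. The mix of alveolar macrophage clusters differed between genotypes. One led by Ear2 and Ctsk held 407, 542 and 312 of 1103, 1857 and 996 cells in WT and 172, 74 and 255 of 818, 531 and 1696 in Tmem175-/-. Of the genes called in the class of monocytes or interstitial macrophages, Ctsd lay at a log2 fold change of 0.18 ± 0.10 (adjusted p = 0.493) and Spp1 at -0.13 ± 0.10 (adjusted p = 0.666). The difference between the macrophage classes was itself tested, as the interaction of genotype and class with the library as a block, and 899 of 12626 genes passed. The effect in monocytes or interstitial macrophages minus that in alveolar macrophages was -1.21 ± 0.09 for Ctsd (adjusted p = 1.09e-05), -1.18 ± 0.11 for Trem2 (adjusted p = 6.03e-05) and -2.15 ± 0.29 for Mmp12 (adjusted p = 0.00314). It was -1.83 ± 0.23 for Spp1 (adjusted p = 0.00591). These genes were chosen after their values were seen. The interaction count was 317 without WT 1 and 580 without Tmem175-/- 3. Genes with the largest increases in alveolar macrophages included Awat1, a wax ester synthase (0.471 ± 0.0745 and 4.59 ± 2.25 CPM, 3.22 ± 0.48, adjusted p = 0.016, or 0.0903 without WT 1). Among the decreases were Shc4 (-3.24 ± 0.52) and Dclk1 (-3.23 ± 0.58), both with a high free RNA share. The 121 calls became 2 without WT 1, 223 without WT 2, 58 without Tmem175-/- 1 and 57 without Tmem175-/- 3. Free RNA was estimated at 6.73, 9.93 and 6.53% of the UMIs in WT and 1.93, 1.55 and 2.1% in Tmem175-/-. The value of WT 2 is uncertain, since scaling by epithelial genes gave 7000 melanocyte UMIs there and 1917 were observed.

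In T cells 359 genes rose and 632 fell among 12197 tested. Of 40 type I interferon stimulated genes, 33 rose (38 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation). They included Isg15, a ubiquitin-like modifier (102 and 244 CPM, log2 fold change 1.33 ± 0.15, adjusted p = 0.000213), and Irf7 (1.09 ± 0.12, adjusted p = 0.000149). The nucleic acid sensor Zbp1 rose (0.87 ± 0.15, adjusted p = 0.00293), as did Oas2 (2.19 ± 0.971 and 8.93 ± 1.1 CPM, 2.09 ± 0.29, adjusted p = 0.000655). In the list of MHC class I presentation 10 of 22 rose (19 adjusted over the list alone, adjusted p = 0.378 with an estimated correlation). The proliferation list had 18 of 32 genes up (19 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation), with Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 0.77 ± 0.14 (adjusted p = 0.0038). The dividing cluster made up 30, 40 and 31 cells of this class in WT and 164, 142 and 138 in Tmem175-/-. Of 20 checkpoint and exhaustion genes, 6 rose (8 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation). They were the inhibitory receptor Lag3 (1.09 ± 0.23, adjusted p = 0.00933), the signalling regulator Rgs16 (0.97 ± 0.17, adjusted p = 0.00334), Ctla4, Nr4a2, Cd160 and, with a high free RNA share, Havcr2. The genes with the largest increases included Itgad, an integrin chain (0.613 ± 0.386 and 3.98 ± 1.09 CPM, 2.72 ± 0.46, adjusted p = 0.00224), C2cd4b (2.39 ± 0.34, adjusted p = 0.000698) and Tmem254 (1.72 ± 0.14, adjusted p = 2.15e-05). The largest decreases were in genes with a high free RNA share, such as Cdh2 (-3.93 ± 0.55) and the melanosome transport gene Mlph (-3.38 ± 0.37), and all 10 melanocyte lineage genes tested fell. Of the 991 calls 334 up and 99 down were without a high free RNA share, and 266 genes were called when such genes alone were tested. Leaving out 1 library gave 674 to 1066.

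Isg15 was called in 3 of the 5 T cell subsets tested, where it was chosen after its values were seen. Isg15 rose by a log2 fold change of 1.10 ± 0.18 in regulatory T cells (adjusted p = 0.00313), by 1.79 ± 0.23 in the group led by Lef1, Dapl1 and Il7r (adjusted p = 0.00159) and by 1.40 ± 0.14 in the group led by Il17a (adjusted p = 8.81e-07). It was not called in CD8 T cells (0.58 ± 0.18, adjusted p = 0.145) or in the dividing group (1.45 ± 0.28, adjusted p = 0.0656). The numbers of genes up and down were 361 and 494 in the Lef1 group, 320 and 302 in the Il17a group, 57 and 149 in CD8 T cells, 13 and 33 in regulatory T cells and 14 and 15 in the dividing group led by H2ac23. Leaving out a library moved the count of the Il17a group from 622 to 355 (WT 1), 368 (Tmem175-/- 2) or 384 (Tmem175-/- 3). That of CD8 T cells went from 206 to 81 (WT 3) or 108 (Tmem175-/- 3), that of regulatory T cells from 46 to 16 (WT 1) or 78 (Tmem175-/- 2), and that of the dividing group from 29 to 14 (Tmem175-/- 3).

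NK cells carried more transcript of some effector genes in Tmem175-/- lungs, with 187 genes up and 257 down among 8440 tested. Of these 181 up and 63 down were without a high free RNA share, and when such genes alone were tested 189 genes and 40 interactions with T cells were called. Of 22 cytotoxic effector genes, 7 rose (8 adjusted over the list alone, adjusted p = 0.315 with an estimated correlation). The chemokine gene Ccl5 went from 19700 to 31400 CPM (log2 fold change 0.77 ± 0.10, adjusted p = 3.8e-06). The maturation receptor Klrg1 changed by 0.85 ± 0.13 (adjusted p = 3.81e-05), and the granzyme gene Gzma by 0.43 ± 0.09 (adjusted p = 0.00336), with Gzmk, Gzmb, Prf1 and Nkg7 also up. Of 25 type I interferon stimulated genes 8 rose (14 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation). Of 22 class I genes 9 rose (14 adjusted over the list alone, adjusted p = 0.41 with an estimated correlation). Cdk2ap1, a regulator of cell cycle and chromatin, had one of the largest increases (39.6 ± 14.1 and 160 ± 11.9 CPM, 2.06 ± 0.17, adjusted p = 9.71e-10). In the proliferation list 1 of 23 genes rose and 4 fell in NK cells (1 and 7 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation). Ube2c lay at -0.95 ± 0.33 (adjusted p = 0.102) and Mki67 at -0.81 ± 0.29 (adjusted p = 0.0999). The effect in NK cells minus that in T cells was -1.68 ± 0.28 for Ube2c (adjusted p = 0.000533) and -1.38 ± 0.28 for Mki67 (adjusted p = 0.00439), genes chosen after their values were seen. In all, 106 of 11575 genes had an interaction. Decreases were led by Nbea (-4.21 ± 0.35) and the melanocyte genes Sox10 (-3.17 ± 0.52) and Oca2 (-3.11 ± 0.56), all with a high free RNA share. Free RNA gave 14.4, 10.6 and 11.8% of NK cell UMIs in WT and 4.35, 4.08 and 4.79% in Tmem175-/-. The count of 444 was 278 without WT 1, 278 without Tmem175-/- 1 and 271 without Tmem175-/- 3, that of interactions was 64 without WT 1, 61 without WT 2 and 29 without WT 3.

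Some interferon and class I genes were called higher in structural cells of the Tmem175-/- lung. Type I interferon stimulated genes rose in 11 of 37 in endothelial, 13 of 40 in mesothelial and 6 of 29 in mural cells (adjusted p = 0.235, 0.315 and 0.225 with an estimated correlation). In fibroblasts 461 genes rose and 264 fell among 13363 tested. Of 41 type I interferon stimulated genes 38 rose (40 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation). Ifit1, an inhibitor of viral RNA translation, lay at a log2 fold change of 2.52 ± 0.25 (adjusted p = 0.00156) and Irf7 at 1.45 ± 0.22 (adjusted p = 0.00785). Of 22 class I genes 15 rose (18 adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). B2m went from 1090 to 2170 CPM (1.04 ± 0.08, adjusted p = 7.51e-05), and H2-D1 changed by 1.25 ± 0.09 (adjusted p = 6.35e-05) and the immunoproteasome subunit Psmb8 by 1.23 ± 0.21 (adjusted p = 0.0123). The mix of fibroblast clusters differed between genotypes. One led by Timp1, Eln and Tnc held 768 cells, of which 50, 36 and 71 came from Tmem175-/-. One led by Dcn, Clec3b and Pi16 held 609, 644 and 441 of 1556, 2059 and 1406 fibroblasts in WT and 602, 396 and 492 of 1180, 855 and 1002 in Tmem175-/-. Of 27 extracellular matrix genes 9 fell (16 down and 1 up adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). Among them were the basement membrane collagens Col4a1 (-0.63 ± 0.11, adjusted p = 0.00994) and Col4a2 (-0.66 ± 0.12, adjusted p = 0.00885) and the matricellular gene Thbs1 (-0.54 ± 0.08, adjusted p = 0.00327). NK cell genes such as Klra7 (4.23 ± 0.55) and Eomes (4.21 ± 0.61) were among the largest increases and had a high free RNA share. Endothelial cells had 153 genes up and 97 down among 9777. Of these 76 up and 14 down were without a high free RNA share, and 86 genes were called when such genes alone were tested. Of 22 class I genes 14 rose (17 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation) and H2-K1 at 1.04 ± 0.12 (adjusted p = 0.000196). Mesothelial cells, the lining of the pleura, had 163 up and 51 down among 10788. Of 22 class I genes 13 rose (14 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation), with H2-K1 at 0.93 ± 0.13 (adjusted p = 0.00209). Mural cells had 16 up and 7 down among 8336, with Ifi27l2a, an interferon-inducible mitochondrial protein, at 187 ± 35.2 and 818 ± 132 CPM (2.15 ± 0.17, adjusted p = 1.79e-05). Free RNA was estimated at 34.8, 60 and 11.3% of endothelial UMIs in WT and 4.14, 5.68 and 4.56% in Tmem175-/-. The value of WT 2 is uncertain, since scaling by epithelial genes gave 5030 melanocyte UMIs there and 673 were observed. In fibroblasts free RNA was estimated at 8.04, 11 and 6.99% in WT against 3.23, 2.17 and 3.09% in Tmem175-/-. There too the value of WT 2 is uncertain, with 7210 melanocyte UMIs by epithelial genes and 2947 observed. The fibroblast count of 725 was 473 when genes without a high free RNA share alone were tested, 360 without WT 1, 383, 398 and 402 without Tmem175-/- 1, 2 and 3. The endothelial count of 250 was 150 without WT 1, 165 without WT 3 and 141 without Tmem175-/- 3. The mesothelial count of 214 was 76 without WT 1, and the mural count of 23 was 13 without Tmem175-/- 2 and 7 without Tmem175-/- 3.

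Melanoma cells, which carry the genome of the injected line and not that of the mouse, had 39 genes up and 1 down among 15671 tested. Of 22 class I genes 5 rose (13 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation). H2-K1 lay at 40.5 and 81.6 CPM (log2 fold change 0.96 ± 0.11, adjusted p = 0.00775), B2m at 0.75 ± 0.10 (adjusted p = 0.013) and H2-D1 at 0.74 ± 0.10 (adjusted p = 0.0165). Isg15 rose from 33 ± 8.03 to 110 ± 25.5 CPM (1.68 ± 0.24, adjusted p = 0.0444) as 1 of 2 type I interferon stimulated genes called among 40 (25 adjusted over the list alone, adjusted p = 0.315 with an estimated correlation). Cdk2ap1 was among the largest increases (55.7 ± 21.5 and 240 ± 18.8 CPM, 2.08 ± 0.22, adjusted p = 0.0113). The melanocyte lineage genes of these cells had a median log2 fold change of -0.18 with 0 of 10 called by edgeR, and camera called the list lower (adjusted p = 0.0319, or 0.378 with an estimated correlation). Gzma (1.75 ± 0.20) and Nkg7 (1.73 ± 0.19), genes of cytotoxic lymphocytes, rose with a high free RNA share, and Hbb-bs, a hemoglobin gene with a high free RNA share, was the one that fell (-6.03 ± 0.50). The count of 40 was 65 when genes without a high free RNA share alone were tested, 22 without WT 1, 217 without WT 3 and 0 without Tmem175-/- 3, and the call of H2-K1 ended without Tmem175-/- 3 (adjusted p = 0.0731). The B2m call ended without Tmem175-/- 1 (0.0721) or Tmem175-/- 3 (0.128), and the H2-D1 call without WT 1 (0.102), Tmem175-/- 1 (0.0814) or Tmem175-/- 3 (0.156). The Cdk2ap1 call ended without WT 2 (0.0517) or Tmem175-/- 3 (0.064). The Isg15 call ended without WT 1 (0.0584), WT 2 (0.118), Tmem175-/- 1 (0.0814), Tmem175-/- 2 (0.111) or Tmem175-/- 3 (0.0637).

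In neutrophils 277 genes rose and 971 fell among 7380 tested, and most of the decreases were in genes with a high free RNA share, such as the melanocyte gene Trpm1 (-3.01 ± 0.29). At a Leiden resolution of 2.5 the mix of clusters in this class differed, with 266, 294 and 101 cells in WT and 1031, 483 and 1000 in Tmem175-/- in one, and 383, 945 and 243 against 378, 223 and 253 in another. Of 35 type I interferon stimulated genes 21 rose (29 adjusted over the list alone, adjusted p = 0.378 with an estimated correlation). Oas1g lay at 12.5 ± 3.15 and 44.4 ± 3.85 CPM (log2 fold change 2.01 ± 0.24, adjusted p = 0.000105) and Ifi27l2a at 1.76 ± 0.25 (adjusted p = 0.000365). The class I gene H2-Q7, whose reads can be shared with H2-Q6 and are uncertain, rose from 41.1 ± 5.84 to 224 ± 83.5 CPM (2.54 ± 0.28, adjusted p = 8.28e-05). Of 57 nuclear genes of oxidative phosphorylation 33 fell (42 adjusted over the list alone, adjusted p = 0.329 with an estimated correlation). Free RNA was estimated at 19.4, 15.7 and 15.7% of neutrophil UMIs in WT and 16.6, 5.57 and 4.37% in Tmem175-/-. The value of Tmem175-/- 1 is uncertain, since scaling by epithelial genes gave 1390 melanocyte UMIs and 506 were observed. The genes without a high free RNA share had a median log2 fold change of 0.26, and when these alone were normalised and tested, the calls were 3: Oas1g, Ifi27l2a and H2-Q7. With all genes the count of 1248 was 510 without WT 1, 794 without WT 3 and 824 without Tmem175-/- 2.

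The remaining classes had 5 to 381 called genes. B cells had 122 genes up and 259 down among 11457. Of these 105 up and 9 down were without a high free RNA share, and 46 genes were called when such genes alone were tested. Free RNA gave 15.7, 8.17 and 11.5% of B cell UMIs in WT and 3.8, 3.91 and 5.33% in Tmem175-/-. The mix of B cell clusters differed too, with 793, 808 and 623 cells in WT and 655, 1050 and 1074 in Tmem175-/- in one, and 212, 445 and 364 against 710, 2548 and 1338 in another. Of 39 type I interferon stimulated genes 19 rose (33 adjusted over the list alone, adjusted p = 0.26 with an estimated correlation). Ifi208, a member of an interferon-inducible DNA sensor family, lay at 0.939 ± 0.678 and 17.7 ± 2.48 CPM (log2 fold change 4.25 ± 0.34, adjusted p = 0.000104). The hemoglobin gene Hbb-bt fell from 74 ± 3.13 to 6 ± 2.42 CPM in B cells (-3.46 ± 0.24, adjusted p = 0.000104). Hemoglobin genes mark red cells, and other classes could hold them as free RNA. Dendritic cells had 132 up and 201 down among 11414, of which 114 up and 79 down were without a high free RNA share, and 162 genes were called when such genes alone were tested. Of 22 class I genes 8 rose (16 adjusted over the list alone, adjusted p = 0.315 with an estimated correlation), and Batf2, a transcription factor induced by interferon gamma, lay at 2.68 ± 0.42 (adjusted p = 0.00289). Plasmacytoid dendritic cells, the main producers of type I interferon, had 10 up and 2 down among 2387, among them Irf7 at 172 ± 45.3 and 478 ± 76.8 CPM (1.47 ± 0.23, adjusted p = 0.000254). Group 2 innate lymphoid cells had 22 up and 36 down among 4194, of which 17 and 2 were without a high free RNA share, and 8 genes were called when such genes alone were tested. Among the increases was Stab2, a scavenger receptor gene (127 ± 9.5 and 394 ± 36.8 CPM, 1.69 ± 0.20, adjusted p = 6.61e-05). Epithelial cells had 5 up and 0 down among 11644, among them the mucin gene Muc5ac (1.58 ± 1.16 and 27.3 ± 4.69 CPM, 4.02 ± 0.40, adjusted p = 0.00808). Leaving out a library moved the B cell count of 381 to 84 (WT 1), 15 (WT 3), 937 (Tmem175-/- 1), 143 (Tmem175-/- 2) or 221 (Tmem175-/- 3). That of dendritic cells went from 333 to 190 (WT 1) or 196 (Tmem175-/- 2), and that of plasmacytoid dendritic cells from 12 to 7 (WT 1), 21 (WT 2) or 30 (Tmem175-/- 2). The count of innate lymphoid cells went from 58 to 29 without WT 1 or Tmem175-/- 2, and that of epithelial cells from 5 to 2 (WT 1), 20 (WT 2), 1 (WT 3) or 450 (Tmem175-/- 1).

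Across the 15 classes, the type I interferon list was called higher by camera in 14 and the MHC class I list in 15. None of these calls held with an estimated correlation, and other splits of the 6 libraries gave up to 14 and 15 classes. Median changes of the type I list ranged from 0.24 in alveolar macrophages, the class without a call, to 1.44 in fibroblasts. Genes called higher in the largest numbers of classes included Cdk2ap1 in 13, H2-K1 in 11, and B2m, Ifi27l2a, H2-Q4 and Tmem254 in 10 each. In all, 270 genes rose in 3 or more classes and 409 fell in 3 or more, and 372 of the latter had a high free RNA share in most of those classes. Cdk2ap1 had a high free RNA share in 8 of the 12 host classes where it rose. Among the genes lower in several classes were Wdfy1, an endosomal adaptor of Toll-like receptor signalling, in 9 classes (3 with a high free RNA share), and Zbtb16, a transcription factor of innate-like lymphocytes, in 6 (0). Fkbp5, a glucocorticoid-induced chaperone, was lower in 5 (1), for example in fibroblasts (log2 fold change -1.31 ± 0.19, adjusted p = 0.0045).

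**Figure D3:**
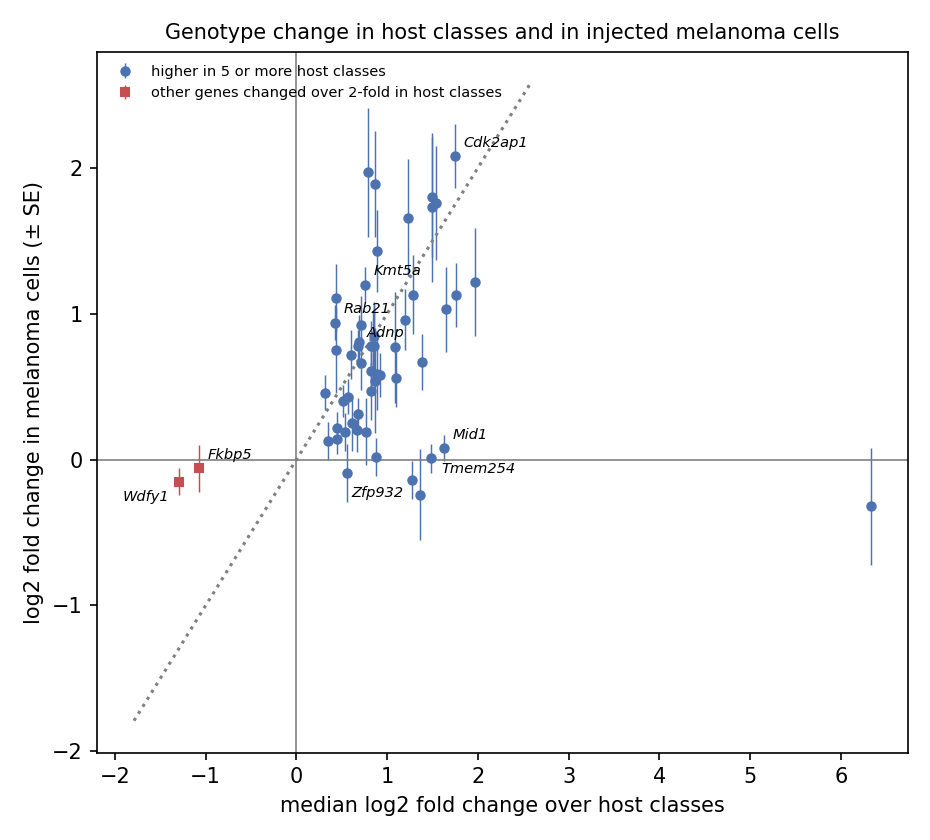
Median log2 fold change of Tmem175-/- against WT over the host classes and the change in melanoma cells with its SE, for genes higher in 5 or more host classes outside the interferon and MHC lists and for other genes changed over 2-fold in host classes. Cdk2ap1 changed by 1.75 in host classes and 2.08 in melanoma cells, and Mid1 by 1.63 and 0.08.

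**Figure D4:**
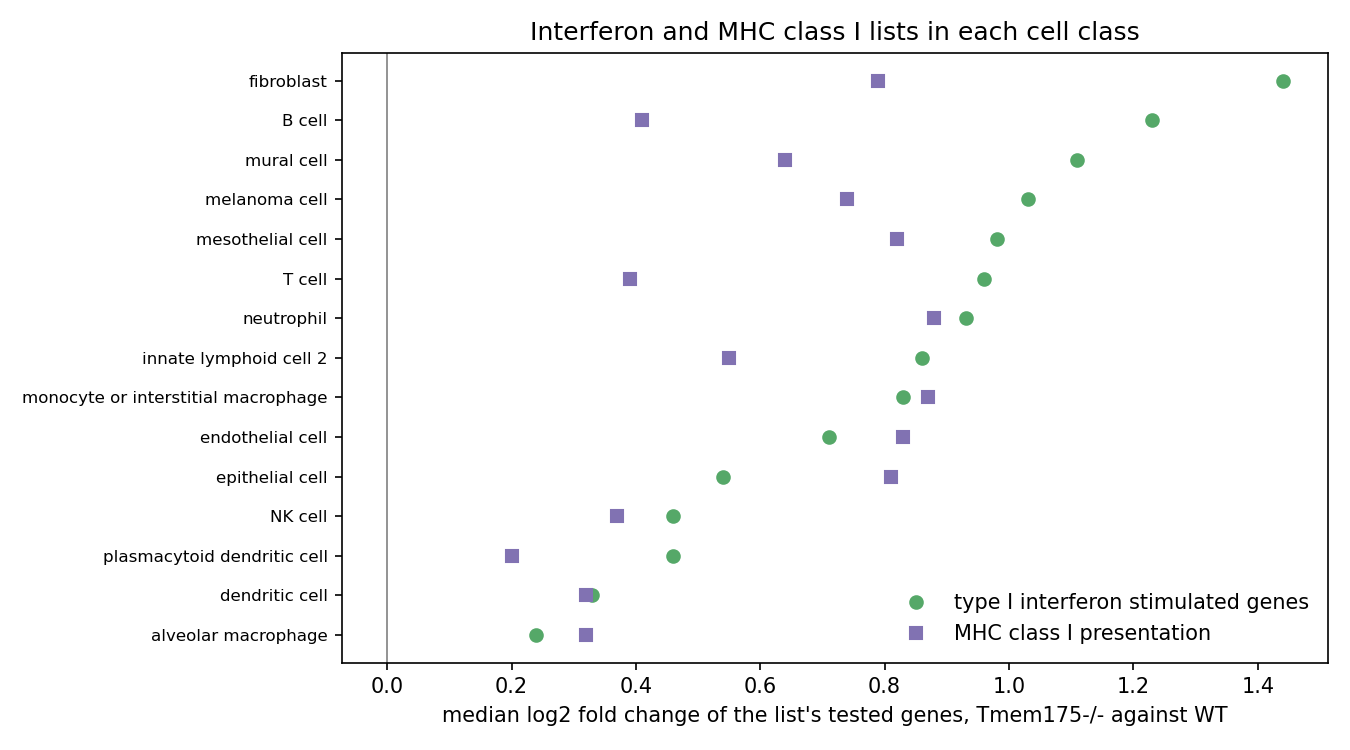
Median log2 fold change of Tmem175-/- against WT over the tested genes of the type I interferon list (circles) and the MHC class I list (squares) in each of 15 cell classes. The medians run from 0.24 to 1.44 for the interferon list and from 0.20 to 0.88 for the class I list, all above 0.

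All 38 lists were tested in each class where 5 or more of their genes were measured, 508 pairs in all, and 211 pairs were called by camera with its preset correlation. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.225 and 80 pairs had an unadjusted p under 0.05, while fry, which tests a list alone, called 44. Besides those above, lists called higher and lower were, in numbers of classes, the interferon gamma response in 13 and 0, MHC class II in 8 and 0, and naive and memory lymphocyte genes in 8 and 0. Cytotoxic genes stood at 7 and 0, immediate early and dissociation genes at 6 and 0, and checkpoint genes at 5 and 0. Lymphocyte activation genes stood at 3 and 0, NK cell receptors at 3 and 1, neutrophil granule genes at 1 and 0, and cell death genes at 1 and 0. Metabolic lists stood at 0 and 13 for oxidative phosphorylation, 0 and 11 for mitochondrially encoded transcripts, 0 and 9 for glycolysis, 1 and 4 for cholesterol synthesis, 0 and 3 for lipid handling, and 1 and 1 for hypoxia. Other splits gave up to 15, 15, 4 and 11 classes lower for the first 4 of these. The list counts include genes with a high free RNA share. The mean expected share of free RNA was higher in WT in all 15 classes. In neutrophils 5 of the 971 genes that fell were without a high free RNA share. Counts per list without such genes are not given here, so how far free RNA accounts for these decreases is left open. Proliferation stood at 2 and 11, extracellular matrix at 0 and 8, lysosomal membrane proteins and V-ATPase at 0 and 7, lysosomal hydrolases at 0 and 2, heat shock at 1 and 5, and the unfolded protein response at 0 and 2. Alternatively activated macrophage genes stood at 0 and 4, phagocytosis at 0 and 2, chemokines at 1 and 2, inflammatory cytokines at 0 and 2, and tumor associated neutrophil genes at 0 and 2. Melanocyte genes stood at 0 and 14, melanoma cells included. Markers of other cells stood at 0 and 3 for hemoglobin, 0 and 4 for airway epithelium, 8 and 0 for B and plasma cells, 2 and 0 for neutrophils and 0 and 1 for endothelium. The lists of lysosomal ion channels, of autophagy and TFEB targets and of endothelial activation were called in no class by camera.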

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

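Tests of the patterns below were chosen only after the result was seen, except those of engulfment by phagocytes and of GC in genes outside the interferon and MHC lists.

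The effect of genotype differed between the macrophage classes, by a test of the interaction that does not separate a response of macrophages from a change in the mix of the class. A cluster named classical monocytes, part of which was named nonclassical at a Leiden resolution of 2.5, held 303, 545 and 124 cells in WT and 1086, 563 and 920 in Tmem175-/-, and in interstitial macrophages alone Ctsd lay at -0.63 against -1.04 in the whole class and Spp1 at -1.58 (adjusted p = 0.146) against -1.98, while Mmp12 at -0.90 and Fabp5 at -1.22 were called. The test called 899 of 12626 genes between monocytes or interstitial macrophages and alveolar macrophages, with Ctsd at -1.21, Mmp12 at -2.15, Trem2 at -1.18 and Spp1 at -1.83 in log2, and 317 without WT 1 or 580 without Tmem175-/- 3. In T cells the cluster of dividing cells went from 30, 40 and 31 cells in WT to 164, 142 and 138 in Tmem175-/-. Between NK and T cells the test called 106 of 11575 genes, with the mitotic genes Ube2c at -1.68 and Mki67 at -1.38, and 64 without WT 1, 61 without WT 2 or 29 without WT 3. The real grouping of the libraries gave 899 and 106 genes, and the highest of the 9 other splits gave 1 and 6. Those splits mix the genotypes within groups, which adds to the spread and can lower their calls. Their low counts therefore cannot tell a genotype effect from a batch that follows the genotype.

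Some cells outside the compared classes were more numerous in a Tmem175-/- library than in every WT library. A cluster led by the recombination genes Rag1 and Dntt, as in immature thymocytes, held 1893 cells in Tmem175-/- 1 against 21 or fewer in the others. A cluster with markers of neutrophils and B cells held 39 cells in Tmem175-/- 2. Clusters with heart muscle genes Myl7 and Sln and with markers of monocytes and neutrophils held 14 and 15 cells in Tmem175-/- 3. The largest unnamed cluster went the other way, with 1257, 347 and 1842 cells in WT and 98, 53 and 73 in Tmem175-/-. It had a median of 610 UMIs and was led by Hbb-bs, with the melanocyte genes Mlana, Trpm1 and Tyrp1 among its leading genes.

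The melanocyte lineage list was called lower by camera in all 14 classes where it was tested, melanoma cells (median log2 fold change -0.18) and 13 others, with medians such as -2.79 in T cells and -2.93 in dendritic cells. No call of these melanocyte genes as a list held with an estimated correlation, and other splits of the libraries gave up to 13 classes lower. The UMIs of these genes outside melanoma and epithelial cells were 1.24 times in WT, and 1.06 times in Tmem175-/-, what the free RNA profile scaled by epithelial genes gives, as medians over classes and libraries. Single ratios ran from 0.134 to 3.27, and WT 2 lay lowest in endothelial cells (0.134), alveolar macrophages (0.274), monocytes or interstitial macrophages (0.298), fibroblasts (0.409) and dendritic cells (0.482), and Tmem175-/- 1 in neutrophils (0.363). Engulfed melanoma cells would raise these UMIs in phagocytes above lymphocytes, and the quotient of the ratios was 0.995 (0.545 to 1.08 per library), which argues against it. The lower level outside melanoma cells could come from free RNA that is more plentiful in WT suspensions, where melanoma cells were more frequent, though the estimate is poor in those classes of WT 2 and Tmem175-/- 1.

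Type I interferon and MHC class I genes were higher across classes. The median of the type I list, taken over classes, was 0.863 in log2. It was 0.683 to 1.06 as 1 library was left out and 0.681 without genes of a high free RNA share, so neither 1 library alone nor those genes explain most of it. Its called genes and those of class I lie at a median GC of 54.9% in their first 200 bases against 59% in all genes, a difference of -4.12 points. This argues against better recovery of GC-rich 5′ ends in Tmem175-/- libraries. The median lay below the central range of random gene sets of the same size, 56.4 to 62%. Better recovery of GC-poor 5′ ends in Tmem175-/- libraries was not tested. A batch that follows the genotype cannot be told apart from it, since every library of a genotype would share it. Other splits of the libraries gave up to 14 classes for the same list by camera. Each of those splits holds the genotypes in unequal numbers in its groups, so part of a genotype effect stays in it. The number of classes called therefore cannot decide whether the pattern follows the genotype.

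Genes outside those lists rose in 5 or more host classes, 55 in all. Their median GC differed from that of all genes by -0.5 points, which argues against recovery of GC-rich 5′ ends as the cause for the set, though 20.4% of them had a GC of 70% or more against 14.2% of genes tested. Of them 4, Adnp, Cdk2ap1, Kmt5a and Rab21, also rose in melanoma cells, which carry another genome. A variant of the host genome alone would not explain that rise, though the 4 were picked by it. Cdk2ap1 and Kmt5a lie on the chromosome of Tmem175, at 459 and 461 genes from it. Cdk2ap1 was no longer called in melanoma cells without WT 2 (adjusted p 0.0517) or Tmem175-/- 3 (0.064), and without Tmem175-/- 3 that class had 0 called genes. Of 34 genes called in 5 or more host classes with a median change over 2-fold, picked by host values and free RNA alone, 6 changed in melanoma cells by under 0.5 times the host change in log2, beyond 2 SE. Among them were Fkbp5, Mid1, Tmem254, Wdfy1 and Zfp932. In 12 of the 34 the melanoma change was over 0.5 times the host change, beyond 2 SE, so recovery that differs between libraries in all their cells cannot be told apart from other causes for the 34 as a set. For the 6, a variant of the host genome or a response of host cells could be the cause. A high free RNA share was found in 62.5% of the calls of Mid1 and 60% of those of Zfp932. Zfp932 lies 45 genes from Tmem175 on the same chromosome, where genes within 60 of it were called in 2 of 37 in T cells (8.12% of all genes) and 1 of 36 in fibroblasts (5.43%).

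The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and for each count below 1 of the 10, the real split, gave as many calls. Real calls and the highest of the other splits were 8658 and 0 over all cells, 2443 and 0 in monocytes or interstitial macrophages, 1248 and 2 in neutrophils, 991 and 0 in T cells, and 725 and 6 in fibroblasts. They were 444 and 4 in NK cells, 381 and 21 in B cells, 333 and 1 in dendritic cells, 250 and 15 in endothelial cells, 214 and 0 in mesothelial cells, and 121 and 0 in alveolar macrophages. Smaller counts were 58 and 6 in innate lymphoid cells, 40 and 0 in melanoma cells, 23 and 2 in mural cells, 12 and 0 in plasmacytoid dendritic cells, and 5 and 0 in epithelial cells. In the finer classes they were 879 and 3 in interstitial macrophages, 855 and 0 in Lef1 T cells, 622 and 0 in Il17a T cells, 256 and 1 in classical monocytes, 206 and 1 in CD8 T cells, and 46 and 2 in regulatory T cells. Dendritic subsets gave 233 and 1, 171 and 4, and 42 and 2, in type 2, type 1 and mature cells, and H2ac23 T cells gave 29 and 2. Shares gave 9 and 0 broad classes and 10 and 0 fine classes. List and class pairs gave 211 and 200, with 121 in the lowest of the other splits. Each other split holds the genotypes in unequal numbers in its groups, so part of a genotype effect stays in it. Camera's count therefore cannot decide whether its calls are specific to the genotype. In edgeR's tests the mixed genotypes add to the spread within the groups of the other splits, which can lower the calls there. The low edgeR counts of those splits therefore cannot tell a genotype effect from a batch that follows the genotype.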

How the results depend on the processing

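Directions held in nearly all alternatives, and counts of calls moved with the libraries used. Of 277 named gene results, 158 kept their direction and their side of the threshold in every alternative run. Other size factors (RLE) kept 275 of 277, DESeq2 258 of 273, no filter on low counts 264 of 277 and the replicate block 263 of 277. Leaving out WT 1, the alternative with the most losses, kept 223 of 276. The filter on genes of a high free RNA share kept 98 of 106. Results that this filter removed or was not run on are not judged by it in the 158. Cells with at least 1000 UMIs kept 251 of 251. The causes of the differences were not tested, except that leaving out libraries leaves fewer samples. Leaving out WT 3 and Tmem175-/- 1 together, named cells alone, the free RNA filter on named genes, lists and differences between classes, all alternatives of the finer classes, and denominators without melanoma cells, without B and Lef1 T cells, or with unnamed cells were chosen after seeing the data. In simulated data 2-fold changes were recovered for 31% of genes in epithelial cells, 44% over all cells and 79% in T cells, an order that does not follow depth, so changes of this size can be missed.

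Leaving out 1 library in turn gave 5256 to 8096 calls over all cells, 1253 to 2454 in monocytes or interstitial macrophages, 510 to 1842 in neutrophils, 674 to 1066 in T cells, 360 to 789 in fibroblasts, and 271 to 584 in NK cells. It gave 15 to 937 in B cells, 190 to 353 in dendritic cells, 141 to 296 in endothelial cells, 76 to 190 in mesothelial cells, 2 to 223 in alveolar macrophages, and 29 to 65 in innate lymphoid cells. It gave 0 to 217 in melanoma cells, 7 to 32 in mural cells, 7 to 30 in plasmacytoid dendritic cells and 1 to 450 in epithelial cells. The finer classes gave 331 to 1071 in interstitial macrophages, 34 to 391 in classical monocytes, 81 to 190 in CD8 T cells, 622 to 1226 in Lef1 T cells, 355 to 614 in Il17a T cells, 16 to 78 in regulatory T cells, and 14 to 36 in H2ac23 T cells. Dendritic subsets gave 136 to 239 (type 2), 72 to 207 (type 1) and 25 to 50 (mature). Shares were called in 2 to 7 broad and 2 to 10 fine classes, list and class pairs in 215 to 237, and interactions in 317 to 835 genes for the macrophage classes and 29 to 141 for NK and T cells. The change of Tmem175 over all cells ran from -0.21 to -0.01.

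Without the filter on low counts, more genes were tested and the counts were 1215 in B cells, 735 in NK cells, 1924 in T cells, 697 in alveolar macrophages, 940 in dendritic cells, 596 in endothelial cells, 136 in epithelial cells and 1569 in fibroblasts. They were 152 in innate lymphoid cells, 192 in melanoma cells, 657 in mesothelial cells, 205 in mural cells and 36 in plasmacytoid dendritic cells. In finer classes they were 1484 in interstitial macrophages, 720 in classical monocytes, 438 in CD8 T cells, 1398 in Lef1 T cells, 142 in regulatory T cells, 1012 in Il17a T cells, 170 in H2ac23 T cells, and 614, 497 and 206 in dendritic cells of type 2, of type 1 and mature. Without genes of a high free RNA share they were 46 in B cells, 189 in NK cells, 266 in T cells, 12 in alveolar macrophages, 162 in dendritic cells, 86 in endothelial cells, 473 in fibroblasts, 8 in innate lymphoid cells, 65 in melanoma cells and 3 in neutrophils. The same filter gave 126 list and class pairs and 40 interaction genes between NK and T cells.

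DESeq2 called 243 genes in NK cells, 266 in alveolar macrophages, 127 in epithelial cells, 34 in innate lymphoid cells, 297 in melanoma cells, 46 in mural cells, 794 in neutrophils, 7 in plasmacytoid dendritic cells, 362 in Il17a T cells and 45 in H2ac23 T cells. Without WT 3 and Tmem175-/- 1 the counts were 149 in NK cells, 627 in T cells, 45 in alveolar macrophages, 330 in epithelial cells, 131 in innate lymphoid cells, 372 in melanoma cells and 119 in mesothelial cells. They were 1458 in monocytes or interstitial macrophages, 48 in mural cells, 770 in neutrophils, 7 in plasmacytoid dendritic cells, 131 in CD8 T cells and 83 in classical monocytes, with 4 fine shares and 37 interaction genes between NK and T cells. With the replicate block they were 293 in alveolar macrophages, 533 in dendritic cells, 34 in epithelial cells, 118 in melanoma cells, 105 in mesothelial cells, 46 in mural cells, 72 in mature and 281 in type 1 dendritic cells, with 4 fine shares. The labels do not say whether the numbers pair the libraries, and they were not taken to. Deviations of libraries of the same number correlated at 0.1, 0.118 and 0.016. Those of other numbers correlated at -0.145 to 0.067, the highest being Tmem175-/- 3 with WT 1. Pairing by number is therefore not excluded. Keeping doublets gave 183 in alveolar macrophages and 18 in epithelial cells, and at most 5% mitochondrial UMIs gave 14 in epithelial cells.

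An exact permutation of the shares, whose smallest p is 0.1, called 0 broad and 0 fine classes, against 9 and 10 by edgeR. Immune classes as denominator left 1 broad and 1 fine class. The denominator without B and Lef1 T cells left 5 broad classes and the denominator without melanoma cells 5 fine classes. Camera with an estimated correlation called 0 pairs (80 at an unadjusted p under 0.05), and fry called 44.

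Some directions reversed. With doublets kept, Ctsg and Mpo over all cells went from -2.35 and -3.58 to 0.88 and 0.69. In alveolar macrophages Atp6v0d2, at 0.01, was -0.02 with doublets kept and -0.01 without genes of a high free RNA share, and ran from -0.08 to 0.05 as libraries were left out. Ctsl there, at -0.08, ran from -0.17 to 0.07. Neither passed the threshold. The share of dendritic cells, at 0.11, was -0.40 among immune classes, -0.08 without melanoma cells in the denominator and -0.08 without WT 3 and Tmem175-/- 1. Among immune classes that of monocytes or interstitial macrophages was -0.15 and that of neutrophils -0.07, and that of neutrophils was -0.07 without WT 3 and Tmem175-/- 1.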

Other observations

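In melanoma cells 4 more genes were called higher, chosen after their values were seen. Relb, a subunit of NF-kappa B, lay at 16.7 and 32.7 CPM (log2 fold change 0.93 ± 0.11, adjusted p = 0.0103), the immediate early gene Nr4a2 at 18 and 44.6 CPM (1.27 ± 0.12, adjusted p = 0.0064), Trib3, a pseudokinase of the stress response, at 0.70 ± 0.09 (adjusted p = 0.013), and Dhx58, a helicase that senses viral RNA, at 1.45 ± 0.22 (adjusted p = 0.0289). Without Tmem175-/- 3 the count of calls in these cells was 0. Of the lists fixed in advance, heat shock genes had a median of -0.12 in these cells and were called lower by camera (adjusted p = 0.00423, or 0.35 with an estimated correlation). The unfolded protein response had a median of -0.19 and was not called (adjusted p = 0.145).

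Xist, expressed from the inactive X chromosome of female cells, lay at 142, 139 and 0.204 CPM in the WT libraries and 244, 322 and 256 CPM in the Tmem175-/- libraries. These values over all cells depend on the share of melanoma cells, where Xist lay at 4.6, 3.17 and 0.131 CPM in WT and 3.64, 3.52 and 5.02 CPM in Tmem175-/-. In T cells it lay at 421, 372 and 0 CPM in WT and 356, 376 and 397 CPM in Tmem175-/-. The Y-linked genes Ddx3y and Uty had 3 or fewer UMIs in every library. WT 3 held 19 UMIs of Xist, 3 of Uty and 0 of Ddx3y. The sex of the mice is not given in the sources used here.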
